A study of Mus musculus with 17 samples.

How the data were processed

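RNA of 17 mammary samples was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The deposited table holds log2 values for 35556 probe sets. Per the submitters' processing notes the values were made by RMA, a background correction, normalisation between arrays and summary of probes into probe sets, in Partek 5.6; other settings and the genome build are not given in the sources used here. No value was missing (0), and 0 array columns stayed unmapped. The number of arrays limits the precision of every comparison.

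A gene was a symbol held alone by a probe set. Of the probe sets 21789 carried 1 symbol, 1621 several and 12146 none here; 21698 of the 1-symbol probe sets matched the mouse gene table by Entrez ID, which changed 0 symbols. Where several probe sets carried the same symbol, that with the highest mean over all arrays was kept and 1851 were dropped, which left 19938 genes. Trp53 and Cdkn1a did not have a probe set of their own under this rule and were not analysed here. Gene order along chromosomes came from the GRCm38 gene table and served only to place neighbours, so no coordinates are given.

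The groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined. Rb/p53 tumours (n = 9) were compared with p53 tumours (n = 3) on the 12 tumour arrays, and each tumour genotype with normal tissue (n = 5) on all 17 arrays as 3 groups. The tumour against normal comparisons share their controls, so no overlap between them is counted. Ad-Cre (n = 2) and MMTV-Cre (n = 7) Rb/p53 tumours were compared on the 12 tumour arrays as 3 groups, and transplanted (n = 5) with other MMTV-Cre Rb/p53 tumours (n = 2) on those 7 arrays. The p53 replicate 3 array was placed by its source name, description and tissue, against its title.

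Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, sides not chosen in advance), and p was adjusted by the Benjamini-Hochberg method over the 19938 genes, with a threshold of 0.05. Folds are log2 differences of group means with their standard error. Levels are means of log2 values with their SD. Values at an unadjusted p below 0.05 are counted where calls are few.

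The 24 gene lists cover E2F targets and DNA replication, mitosis, p53 targets, mitochondrial translation, oxidative phosphorylation, hypoxia and glycolysis, ribosome biogenesis, luminal, basal, mesenchymal transition, fibroblast, adipocyte, milk protein, T and NK cell, B and plasma cell, macrophage, neutrophil, endothelial, skeletal muscle, erythrocyte, squamous keratinocyte, interferon response, antigen presentation and immediate early genes. Each list with at least 5 measured members was tested with camera at its preset correlation of 0.01, which treats members as nearly independent, and p was adjusted over the lists of a comparison. Camera was run again with a correlation estimated for each list, and with ranks. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Where a list's median is given, it is the median log2 fold of its members.

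Genes are named by rule. In each comparison these are Rb1 and Trp53, the 6 largest rises and 6 largest falls past the threshold, members of each called list that passed, and a fixed set. The fixed set holds E2f1, Ccne1, Cdkn2a, Rbl1, Mki67, Cdkn1a, Mdm2, keratins, Trp63, Esr1, Vim, Cdh1, Epcam, Met, Yap1, Birc2, Birc3 and Tufm. The neighbours Tmem123, Dcun1d5, Dync2h1, Capza2, Cav1, Cav2, Tes and St7 were fixed in advance as well, and the scan of windows was chosen after the values were seen. Predicted genes, small RNAs and receptor or immunoglobulin segments were skipped for naming among the largest changes, not for counting. Of the members of a called list up to 2 are given, with the largest change against the list where it was stable. Genes called under alternatives where calls are few were named after their values were seen, as were the immunoglobulin segments.

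Alternatives fixed in advance were an intensity trend with robust eBayes, array weights, leaving out genes with a mean below the 25th percentile, quantile normalisation again, cyclic loess, the mean of a symbol's probe sets, all probe sets, a fold of at least 1 as well, another set of arrays in the fit, and each array left out in turn. Further ones were MMTV-Cre Rb/p53 tumours only, the 2 Rb/p53 tumours not labelled as transplants only, and p53 replicate 3 moved to the Rb/p53 tumours. An alternative chosen after the data were seen left out p53 replicate 2 and moved replicate 3, so that 1 p53 tumour remained; where 1 sample remains in a group, it is taken to vary like the other groups.

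Up to 100 other splits of the arrays compared were tested in the same way for the comparisons between genotypes and with normal tissue. For p53 replicate 2, each list was set against 10000 random lists matched on mean level in 20 bins. Neighbours at the Yap1 and Met regions were scanned in windows of 10 genes over 9674 genes, with 100 shuffled gene orders for comparison. A single array far from the others in its group was sought by Dixon's gap ratio in groups of at least 5.

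The scripts were tested on simulated data with 19938 genes in each comparison, in which 67, 67 and 66 genes were shifted by 0.5, 1 and 2 log2 units. In Rb/p53 against p53 tumours 22, 56 and 65 of these were recovered, and 12 unchanged genes were called. In Rb/p53 tumours against normal tissue the counts were 20, 58 and 64, with 9 unchanged genes called, and in p53 tumours against normal tissue 12, 45 and 65, with 2. For Ad-Cre against MMTV-Cre tumours they were 2, 32 and 63, with 8, and for transplanted against other tumours 2, 36 and 58, with 8. A list shifted by 0.5 was called in each comparison and 0 other lists were. The simulated noise was independent between genes and held no array that stood apart. The simulation thus does not test list calls where members of a list vary together.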

Results

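RNA was profiled from 12 mouse mammary tumours and 5 samples of normal mammary tissue, all on a mixed strain background. The 9 Rb/p53 tumours lacked both Rb1, which encodes the retinoblastoma protein that restrains the E2F transcription factors, and Trp53, which encodes the tumour suppressor p53, according to the labels. In 7 of them Cre recombinase, which removes DNA between its recognition sites, was expressed under the mouse mammary tumour virus promoter (MMTV-Cre), and in 2 it was carried by adenovirus (Ad-Cre). MMTV-Cre replicate 1 came from a nulliparous and replicate 2 from a parous mouse, while replicates 3 to 7 and both Ad-Cre tumours are labelled as transplants. The 3 p53 tumours arose with MMTV-Cre and deletion of p53 alone. The title of p53 replicate 3 names the Rb/p53 model, whereas its source name, description and tissue name p53 deletion. It was kept with the p53 tumours. The 5 normal samples came from mice of the Rb/p53 model. The tumours are described as independent. Whether each normal sample came from its own animal is not given, so the p-values measure the spread between these samples.

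Each array carried 35556 probe sets, and the number of arrays limits the precision of every comparison. Across these probe sets, arrays of Rb/p53 tumours correlated with each other at r = 0.959 to 0.985 and those of normal tissue at 0.978 to 0.993. The p53 replicate 2 array stood apart: it correlated with the other arrays at 0.888 to 0.915, while all other pairs reached 0.929 or more. Its interquartile range was 2.39 log2 units against 2.91 to 3.18 on the others. In a principal component analysis of the 19938 genes tested, it alone had a high score (109) on the second component. That component held 18.5% of the variance. The first component, with 42.0%, separated normal tissue from tumours.

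Rb1, the targeted gene on the array, was lower in Rb/p53 tumours than in normal tissue (log2 fold -1.67 ± 0.16 SE, limma adjusted p = 7.74e-07). Its level was 9.54 ± 0.23 (SD, n = 9) in Rb/p53 tumours, 10.40 ± 0.54 (SD, n = 3) in p53 tumours and 11.21 ± 0.27 (SD, n = 5) in normal tissue. Rb1 also fell in p53 tumours against normal tissue (log2 fold -0.81 ± 0.21, adjusted p = 0.0124). That call was lost without p53 replicate 1 (-0.58, adjusted p = 0.0751), and without p53 replicate 2 the fold was -1.11. The call was also lost with only the arrays compared in the fit and with p53 replicate 3 moved to the Rb/p53 tumours. The p53 tumours read 9.93 and 10.27 for replicates 1 and 3, while replicate 2 lay above the lowest normal sample (10.93). Replicate 1 thus lay level with the highest Rb/p53 tumour at 9.92. Between the tumour genotypes Rb1 did not pass the threshold (log2 fold -0.86 ± 0.20, adjusted p = 0.112), with -0.56 and adjusted p = 0.407 without p53 replicate 2; without p53 replicate 3 it passed (-0.93, adjusted p = 0.0469). The deleted exons are not given in the sources used here, and a whole-transcript probe set keeps signal from exons that remain, so a residual Rb1 level neither proves nor excludes deletion in a tumour. Trp53 had no probe set of its own under the gene rule and was not analysed here.

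**Figure D1:**
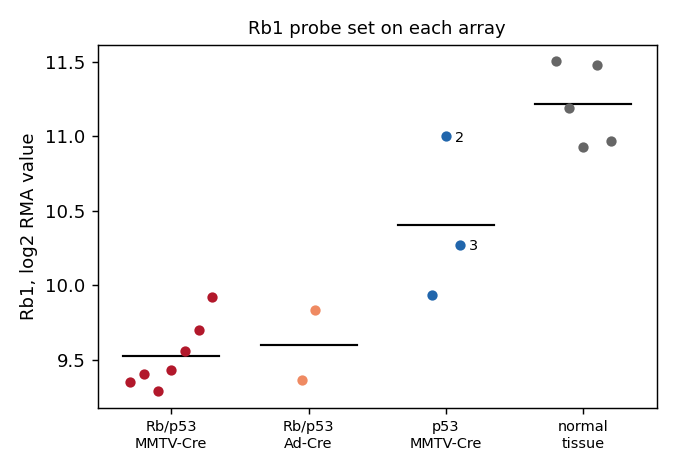
Rb1 level on each of the 17 arrays, as the log2 RMA value on the vertical axis, by group on the horizontal axis. Points are arrays, horizontal lines are group means, and the digits 2 and 3 mark those p53 replicates; Rb/p53 tumours lie between 9.29 and 9.92 and normal tissue between 10.93 and 11.50.

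Rb/p53 tumours against normal mammary tissue ask which genes differ in tumours that lost both suppressors. Of these tumours 7 are labelled as transplants, so a fold can rest on transplants. The mean adipocyte level was 12.81 in normal tissue and 8.58 in Rb/p53 tumours. Cell type markers thus differed as well, and a fold need not be a change within tumour cells. By the list test adipocyte, luminal and basal markers were lower, and E2F targets with DNA replication genes and mitosis genes were higher. With an estimated correlation the adipocyte and basal calls held (adjusted p = 0.00709 and 0.0108), and those on luminal, E2F and mitosis lists were lost (adjusted p = 0.0945, 0.404 and 0.390). Adipoq, the adipocyte hormone adiponectin, fell from 12.95 ± 0.29 (SD, n = 5) to 6.77 ± 0.86 (SD, n = 9), a log2 fold of -6.18 ± 0.37 (adjusted p = 1.66e-09). Brinp3 rose from 7.70 ± 0.35 (SD, n = 5) to 12.25 ± 0.34 (SD, n = 9), a log2 fold of 4.55 ± 0.23 (adjusted p = 1.76e-10). In all, 5503 genes changed by limma at an adjusted p below 0.05, 2828 higher and 2675 lower; 630 and 1000 of these did so by at least 1 log2 unit. Higher calls made up 51.4% of them, and 42.6% (2304 higher, 3103 lower) under cyclic loess.

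The other largest rises in Rb/p53 tumours were those of Dynap at 4.58 ± 0.70, of the granzymes Gzmd at 3.97 ± 0.63 and Gzmc at 3.67 ± 0.40, proteases of cytotoxic lymphocytes, of Ptgs2, the inducible cyclooxygenase, at 3.84 ± 0.46, and of Mmp13, a collagenase, at 3.84 ± 0.83 (log2 fold ± SE, n = 9 and 5). Besides Adipoq, the largest falls were those of Tmem45b (-6.11 ± 0.14), Retnla, a resistin-like cytokine (-6.10 ± 0.59), Cyp2e1, a cytochrome P450 (-5.97 ± 0.52), Gys2, a glycogen synthase (-5.81 ± 0.10), and Aqp7, the glycerol channel of adipocytes (-5.72 ± 0.15). Among the tumours Gzmd and Mmp13 had SDs of 1.43 and 2.01. Gys2 read 5.64 to 6.04 in Rb/p53 tumours, and Gzmd and Gzmc read 4.87 to 5.15 and 5.53 to 5.88 in normal tissue. These lie below 6.37, the lowest 25th percentile of probe sets on any array, so they are not shown to be above background. Adipoq, Retnla, Cyp2e1 and Aqp7 were below it in some Rb/p53 tumours as well. The sizes of these folds are thus not exact.

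Of the 40 measured E2F targets and DNA replication genes, 26 rose, none fell and 14 did not pass the test (median log2 fold 0.90, camera adjusted p = 9.61e-09); 31 rose when adjusted over the list alone. The adjusted p was 0.404 with an estimated correlation. Rfc3, a subunit of the clamp loader, rose by 1.60 ± 0.34, and Rrm2, a ribonucleotide reductase subunit, by 1.41 ± 0.45. Of 27 mitosis genes 23 rose (27 adjusted over the list alone; median 1.45, adjusted p = 1.51e-09, or adjusted p = 0.390 with an estimated correlation). Prc1, a spindle midzone protein, rose by 1.92 ± 0.44 and the kinesin Kif20a by 1.79 ± 0.43. E2f1 rose by 0.71 ± 0.21 and Ccne1, cyclin E1, by 1.06 ± 0.26, whereas Mki67 (0.78 ± 0.35, adjusted p = 0.109) and Rbl1, which encodes the Rb relative p107 (0.37 ± 0.24, adjusted p = 0.298), did not pass. Normal samples themselves spread widely, with means over the E2F list of 8.02 to 9.83 against 9.64 to 10.23 in Rb/p53 tumours. Without normal replicate 1 the calls on Rrm2 (0.96, adjusted p = 0.105) and E2f1 (0.52, adjusted p = 0.0692) were lost, as was that on Rrm2 without normal replicate 4 and with only MMTV-Cre tumours.

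Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, rose by 2.75 ± 0.41 (adjusted p = 7.74e-05), from 7.58 ± 0.14 (SD, n = 5) to 10.34 ± 0.84 (SD, n = 9). Of 26 p53 target genes 6 rose and 4 fell (7 and 4 adjusted over the list alone), and the list did not pass (median 0.11, camera adjusted p = 0.440). Mdm2, a p53 target that degrades p53, was at 9.88 ± 0.24 (SD, n = 9) and 9.80 ± 0.15 (SD, n = 5), with an adjusted p of 0.674. Of 19 ribosome biogenesis genes 5 rose (6 adjusted over the list alone; median 0.51, adjusted p = 0.00175, or adjusted p = 0.536 with an estimated correlation). Pes1 rose by 0.71 ± 0.15 and Mybbp1a by 0.58 ± 0.18. The call on Mybbp1a was lost without normal replicate 1, 3 or 4 (highest adjusted p = 0.0844) and under cyclic loess.

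Genes of the respiratory chain were lower: 28 of 59 oxidative phosphorylation genes fell and none rose (29 fell adjusted over the list alone; median -0.30, adjusted p = 2.88e-09, or adjusted p = 0.339 with an estimated correlation). The cytochrome oxidase subunit Cox6b1 fell by 0.87 ± 0.20 and the complex I subunit Ndufs3 by 0.70 ± 0.10. Under cyclic loess the list median was -0.48. Normal samples spread in mean level over this list, from 10.95 to 11.54, and overlapped the 10.81 to 11.03 of Rb/p53 tumours. Of 73 mitochondrial translation genes 7 rose and 6 fell (5 and 4 adjusted over the list alone; median 0.07, adjusted p = 0.460), and Tufm, the mitochondrial elongation factor Tu, stayed within error (-0.04 ± 0.13, adjusted p = 0.873). Of 18 hypoxia and glycolysis genes 6 rose (6 adjusted over the list alone; median 0.21, adjusted p = 0.0281, or adjusted p = 0.557 with an estimated correlation). The glycolytic kinase Pgk1 rose by 1.54 ± 0.20 and the glucose transporter Slc2a1 by 1.49 ± 0.20. This list's call was lost without Rb/p53 MMTV-Cre replicate 2 (0.13, adjusted p = 0.0692), without normal replicate 5 (0.12, adjusted p = 0.0969), under cyclic loess (0.05, adjusted p = 0.106), with array weights, with the low filter, after quantile normalisation again and with ranks.

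All 17 measured adipocyte genes fell (17 adjusted over the list alone; median -4.33, camera adjusted p = 6.11e-31), and this call held with an estimated correlation (adjusted p = 0.00709). Lep, the adipocyte hormone leptin, fell by 5.59 ± 0.19. Of 27 luminal and epithelial markers 20 fell and none rose (23 fell adjusted over the list alone; median -1.60, adjusted p = 2.77e-13, or adjusted p = 0.0945 with an estimated correlation). Elf5 and Ehf, transcription factors of the mammary epithelium, changed by -3.86 ± 0.43 and -3.28 ± 0.54. Epcam (-2.65 ± 0.71) and Cdh1, E-cadherin (-2.35 ± 0.39), fell as well, as did the oestrogen receptor gene Esr1 (-1.76 ± 0.14), whereas the luminal keratins Krt8 (-0.02 ± 0.45, adjusted p = 0.985) and Krt18 (-0.97 ± 0.51, adjusted p = 0.185) did not pass. Of 19 basal and myoepithelial markers 13 fell (14 adjusted over the list alone; median -1.03, adjusted p = 7.88e-11), and the call held with an estimated correlation (adjusted p = 0.0108). Krt5, a basal keratin, fell by 3.77 ± 0.33, Myh11, smooth muscle myosin, by 2.74 ± 0.12, and Krt14 by 1.51 ± 0.40. Trp63, a basal transcription factor, fell from 9.43 ± 0.21 (SD, n = 5) to 8.23 ± 0.27 (SD, n = 9).

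Among 22 mesenchymal transition markers 12 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.78, adjusted p = 2.28e-04, or adjusted p = 0.180 with an estimated correlation). Tnc, the matrix protein tenascin C, rose by 3.47 ± 0.50 and S100a4 by 3.02 ± 0.37, while the transcription factor Zeb2 fell by 0.94 ± 0.16. Vim, vimentin, rose by 0.22 ± 0.06, a call lost under cyclic loess (0.07, adjusted p = 0.354). Of 18 fibroblast and matrix markers 4 fell (3 adjusted over the list alone) and the list did not pass (median -0.18, adjusted p = 0.0824), though it was called lower without Rb/p53 MMTV-Cre replicate 1 or 3 or Ad-Cre replicate 2 (lowest adjusted p = 0.0386). Of 11 milk protein genes 5 fell (6 adjusted over the list alone; median -1.98, adjusted p = 0.00560, or adjusted p = 0.404 with an estimated correlation). They include the casein Csn2 (-3.11 ± 0.91) and the lipase Cel (-2.37 ± 0.33).

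Markers of other cell types differed between tumours and normal tissue too. Of 17 macrophage markers 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.75, adjusted p = 0.00208, or adjusted p = 0.404 with an estimated correlation). The scavenger receptor Msr1 rose by 2.44 ± 0.27 and the chemokine receptor Cx3cr1 by 1.89 ± 0.34, and Cd163, a haemoglobin scavenger receptor, fell by 2.23 ± 0.44. Of 13 neutrophil markers 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.08, adjusted p = 0.0633), a list called higher without Rb/p53 MMTV-Cre replicate 4 (1.26, adjusted p = 0.0228) or p53 replicate 2 (adjusted p = 0.0319). Of 16 T and NK cell markers 6 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.24, adjusted p = 0.00913, or adjusted p = 0.390 with an estimated correlation). Cd3g and Cd3e, CD3 subunits of the T cell receptor complex, fell by 2.06 ± 0.35 and 0.93 ± 0.17, and granzyme B, Gzmb, rose by 1.34 ± 0.43. The call on Gzmb was lost without normal replicate 1, 2, 4 or 5 (adjusted p = 0.0685 without replicate 1), with only MMTV-Cre tumours and with p53 replicate 3 moved. Of 13 B and plasma cell markers 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.40, adjusted p = 0.00109, or adjusted p = 0.0945 with an estimated correlation). Among them was the immunoglobulin joining chain Jchain (-4.12 ± 0.76). Jchain read 5.33 to 5.74 in Rb/p53 transplants and 8.71 and 10.66 in MMTV-Cre replicates 1 and 2. Normal tissue read 9.84 to 11.19. In the same order the B and plasma cell list had means of 6.58 to 6.72, 6.96 and 7.07, and 7.22 to 7.38. Cd3g read 6.21 to 6.95, 7.57 and 7.88, and 8.67 to 9.20. These falls were larger in transplants, and transplantation was not separated from genotype here. The transplant readings of Jchain are not shown to be above background.

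Of 14 endothelial markers 5 fell (5 adjusted over the list alone; median -0.48, adjusted p = 3.15e-04, or adjusted p = 0.404 with an estimated correlation). The angiopoietin receptor Tek fell by 2.24 ± 0.23. Of 15 skeletal muscle genes 11 fell (13 adjusted over the list alone; median -1.14, adjusted p = 4.81e-06, or adjusted p = 0.390 with an estimated correlation). The myosin light chain Myl1 fell from 11.53 ± 0.47 (SD, n = 5) to 6.52 ± 1.13 (SD, n = 9). Normal samples differed in this list, from 7.60 to 9.74 in mean level, while Rb/p53 tumours lay between 7.06 and 7.68. Of 16 interferon response genes 4 rose (4 adjusted over the list alone; median 0.37, adjusted p = 0.0232, or adjusted p = 0.557 with an estimated correlation). The chemokine Cxcl10 rose by 2.76 ± 0.44. Without Rb/p53 MMTV-Cre replicate 3 the interferon median was 0.31 (adjusted p = 0.0579), and the call was also lost with p53 replicate 3 moved, with the low filter and after quantile normalisation again. Of 13 immediate early genes 4 rose (4 and 1 lower adjusted over the list alone; median 0.44, adjusted p = 0.0388, or adjusted p = 0.390 with an estimated correlation). Ier3 rose by 1.63 ± 0.28. That list's call was lost without Rb/p53 MMTV-Cre replicate 2, 4 or 6, p53 replicate 2, or normal replicate 3 or 5 (highest adjusted p = 0.0704), and with array weights (0.37, adjusted p = 0.110), the low filter, either renormalisation, only the arrays compared in the fit, or p53 replicate 3 moved. Antigen presentation (median -0.27, adjusted p = 0.252) and squamous keratinocyte markers (median -0.02, adjusted p = 0.252) did not pass. Only 3 of the 10 erythrocyte markers were measured, and that list was not tested; its mean level was 7.44 ± 0.44 (SD, n = 9) in tumours and 7.70 ± 0.21 (SD, n = 5) in normal tissue.

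**Figure D2:**
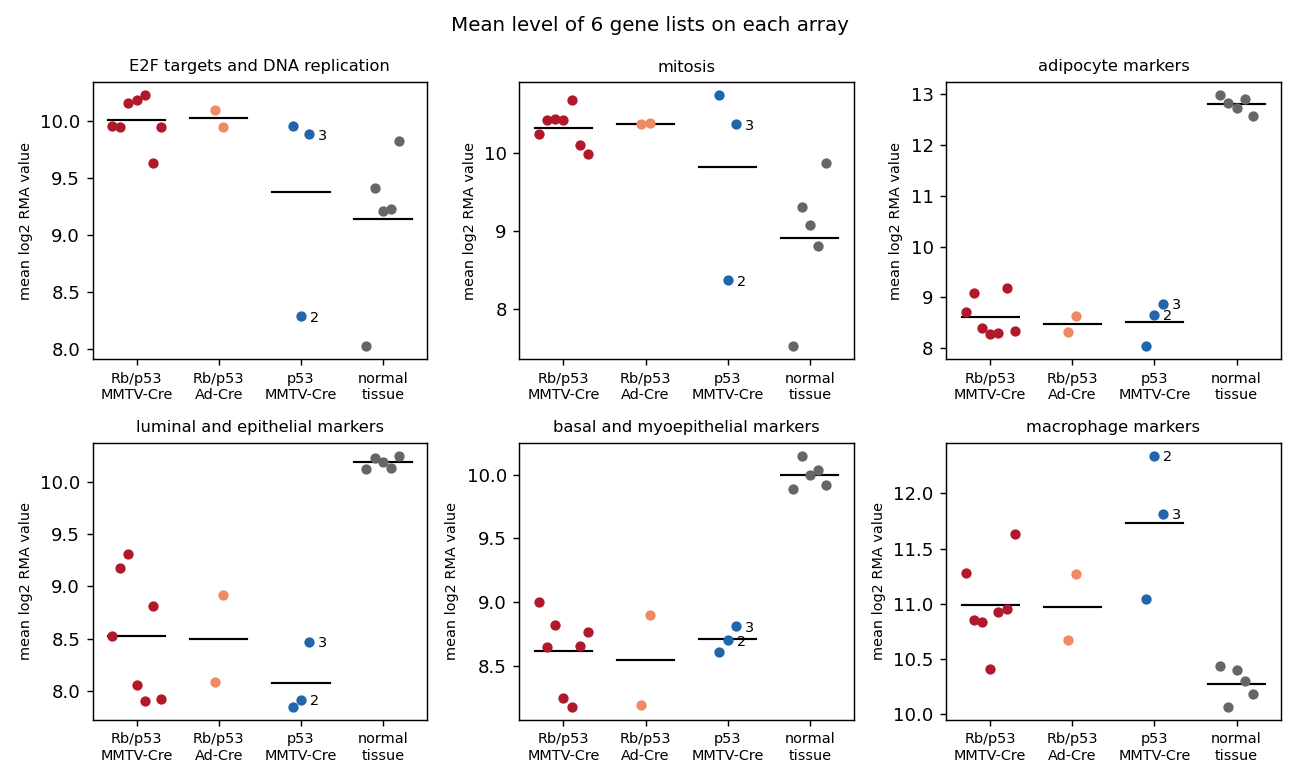
Mean log2 RMA value of 6 gene lists on each array (vertical axes) by group (horizontal axes). Points are arrays, horizontal lines are group means, and the digits 2 and 3 mark those p53 replicates. Adipocyte, luminal and basal lists lie lower in every tumour than in every normal sample; p53 replicate 2 has the lowest E2F level of the tumours, 8.29.

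The p53 tumours were set against the same normal tissue to ask what differs in tumours that lost p53 alone. Their mean adipocyte level was 8.52, against 12.81 in normal tissue, so here too a fold need not be a change within tumour cells. By the list test adipocyte, luminal, basal, milk protein, endothelial and respiratory chain genes were lower in them and macrophage markers higher. With an estimated correlation the adipocyte and basal calls held (adjusted p = 0.00661 and 0.0215), and the others were lost (adjusted p = 0.0781 for luminal markers and 0.338 for each of the rest). Mmp13 rose from 6.76 ± 0.17 (SD, n = 5) to 12.26 ± 1.51 (SD, n = 3), a log2 fold of 5.50 ± 1.09 (adjusted p = 0.00169). Adipoq fell from 12.95 ± 0.29 (SD, n = 5) to 6.73 ± 0.66 (SD, n = 3), a log2 fold of -6.22 ± 0.48 (adjusted p = 1.02e-07). By limma 4073 genes changed, 1663 higher and 2410 lower, with 447 and 1170 of them by at least 1 log2 unit. Higher calls made up 40.8% of these, and 52.8% (2536 higher, 2264 lower) after quantile normalisation was applied again. Without p53 replicate 2, 4233 genes passed, of which 2878 were among the 4073.

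Other large rises in p53 tumours were those of Tnc (4.19 ± 0.66), the C-type lectins Clec4n (4.04 ± 0.46) and Clec4e (3.94 ± 0.75), the collagen Col12a1 (3.98 ± 0.62) and Msr1 (3.79 ± 0.36). The largest falls besides Adipoq were those of Cyp2e1 (-5.97 ± 0.67), the casein Csn1s1 (-5.94 ± 1.26), Tmem45b (-5.93 ± 0.18), the carboxylesterase Ces1d (-5.79 ± 0.77) and Lep (-5.69 ± 0.25). Csn1s1 varied widely among the p53 tumours, with an SD of 3.29. Clec4e read 5.94 to 6.34 in normal tissue and Lep 5.82 to 6.20 in p53 tumours. The lowest 25th percentile of probe sets on any array was 6.37. Adipoq, Cyp2e1, Csn1s1 and Ces1d were below it in some p53 tumours as well. Those readings are not shown to be above background, so the sizes of these folds are not exact. Cdkn2a rose by 2.15 ± 0.53 (adjusted p = 0.00846).

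None of the 40 E2F targets and DNA replication genes passed by limma, over all genes or adjusted over the list alone, and the list was not called (median 0.29, camera adjusted p = 0.253). On p53 replicate 2 its mean level was 8.29, against 9.89 and 9.96 on the other p53 tumours, and without that replicate the list was called higher (median 0.82, adjusted p = 9.27e-07). It was also called without normal replicate 5 (0.40, adjusted p = 0.0249). E2f1 (0.39 ± 0.27), Ccne1 (0.45 ± 0.33), Mki67 (0.69 ± 0.46) and Rbl1 (0.14 ± 0.32) did not pass. Mitosis genes had a median of 0.94 (adjusted p = 0.00104, or adjusted p = 0.800 with an estimated correlation), with 1 of 27 past the threshold, the centromeric histone Cenpa at 0.97 ± 0.31, and 0 adjusted over the list alone. The list's call was lost without p53 replicate 1 (0.44, adjusted p = 0.220) or 3 (0.63, adjusted p = 0.0764), and its median was 1.58 without replicate 2 and 0.63 without normal replicate 1. The call on Cenpa was lost without p53 replicate 1 or 3 or normal replicate 1, 2 or 4, with p53 replicate 3 moved and with only the arrays compared in the fit (highest adjusted p = 0.159), and its fold was 1.52 without p53 replicate 2. Ribosome biogenesis (median 0.28, adjusted p = 0.321), hypoxia and glycolysis (0.13, adjusted p = 0.239) and mesenchymal transition markers (0.39, adjusted p = 0.220) did not pass, and each was called higher without p53 replicate 2 (0.64, adjusted p = 1.08e-04; 0.36, adjusted p = 0.00748; 0.44, adjusted p = 0.00748).

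Of 59 oxidative phosphorylation genes 25 fell and none rose in p53 tumours (30 fell adjusted over the list alone; median -0.38, adjusted p = 2.67e-09, or adjusted p = 0.338 with an estimated correlation). The complex I subunit Ndufab1 fell by 1.09 ± 0.23 and Sdha, a succinate dehydrogenase subunit, by 1.02 ± 0.20. Mean levels of the list overlapped, at 10.73 to 10.99 in p53 tumours and 10.95 to 11.54 in normal tissue. Of 73 mitochondrial translation genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.00993, or adjusted p = 0.800 with an estimated correlation). The mitochondrial ribosomal gene Mrps6 fell by 1.73 ± 0.41 and Mrps9 rose by 0.42 ± 0.10, a call lost with only the arrays compared in the fit. The list rested on p53 replicate 2, without which its median was 0.01 (adjusted p = 0.955) and Mrps6 stood at -1.01, and its call was lost without normal replicate 2 or 3 as well (adjusted p = 0.0628 and 0.105). Array weights, the low filter, quantile normalisation again and cyclic loess each ended the call too (adjusted p = 0.0890 to 0.663). Tufm did not pass (-0.38 ± 0.18, adjusted p = 0.136). Of 26 p53 target genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; median -0.02, adjusted p = 0.809).

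All 17 adipocyte genes fell in p53 tumours (17 adjusted over the list alone; median -4.33, adjusted p = 2.01e-31, and adjusted p = 0.00661 with an estimated correlation). Of 27 luminal markers 20 fell (24 adjusted over the list alone; median -1.91, adjusted p = 1.16e-15, or adjusted p = 0.0781 with an estimated correlation). Elf5 fell from 11.44 ± 0.12 (SD, n = 5) to 7.04 ± 0.70 (SD, n = 3), and Epcam (-4.29 ± 0.92), Cdh1 (-2.27 ± 0.51) and Esr1 (-1.44 ± 0.19) fell too. Krt8 (-0.20 ± 0.58) and Krt18 (-1.77 ± 0.67, adjusted p = 0.0711) did not pass. Of 19 basal markers 12 fell (14 adjusted over the list alone; median -1.27, adjusted p = 2.67e-09, and adjusted p = 0.0215 with an estimated correlation). Examples are Krt5 (-2.93 ± 0.44), Myh11 (-2.60 ± 0.15) and Trp63 (-1.55 ± 0.17). Krt14 fell by 1.57 ± 0.53 (adjusted p = 0.0443), a call lost without p53 replicate 1 or 3, any 1 of normal replicates 1 to 5, Rb/p53 MMTV-Cre replicate 1 or Ad-Cre replicate 1, with p53 replicate 3 moved and under either renormalisation (highest adjusted p = 0.144). Of 11 milk protein genes 7 fell (8 adjusted over the list alone; median -2.96, adjusted p = 6.12e-05, or adjusted p = 0.338 with an estimated correlation). The casein Csn1s2a fell by 5.39 ± 1.32. Fibroblast and matrix markers were called lower (median -0.48, adjusted p = 0.0499, or adjusted p = 0.800 with an estimated correlation). In it 2 of 18 passed over all genes and adjusted over the list alone, the matrix protein Dpt at -3.81 ± 0.48 and the protease Fap at -1.51 ± 0.42. That list's call was lost without p53 replicate 2 (-0.06, adjusted p = 0.581) or 3, normal replicate 1, 2 or 3, Rb/p53 MMTV-Cre replicate 5 or 6, or Ad-Cre replicate 2, and in 5 planned settings (adjusted p = 0.0530 to 0.663). The call on Fap was lost without p53 replicate 2.

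Of 17 macrophage markers 13 rose in p53 tumours (16 adjusted over the list alone; median 1.23, adjusted p = 6.62e-07, or adjusted p = 0.338 with an estimated correlation). Msr1 rose by 3.79 ± 0.36 and Arg1, arginase 1, by 2.69 ± 0.66. Mean macrophage levels were 12.34 on p53 replicate 2 and 11.05 and 11.82 on the other p53 tumours, against 10.06 to 10.43 in normal tissue. Of 13 neutrophil markers 4 rose (7 adjusted over the list alone; median 1.43, adjusted p = 0.0274, or adjusted p = 0.800 with an estimated correlation). The calgranulin S100a9 rose by 2.76 ± 0.68 and the neutrophil collagenase Mmp8 by 2.75 ± 0.55. The neutrophil list lost its call without p53 replicate 2 (0.42, adjusted p = 0.413) and with array weights (0.59, adjusted p = 0.201). Without that replicate S100a9 stood at 1.49 and Mmp8 at 1.83. Endothelial genes were lower, with 8 of 14 fallen (8 adjusted over the list alone; median -0.89, adjusted p = 9.82e-07, or adjusted p = 0.338 with an estimated correlation). Tek changed by -2.43 ± 0.30. Their median was -0.42 without p53 replicate 2. Of 15 skeletal muscle genes 4 fell (9 adjusted over the list alone; median -1.23, adjusted p = 4.57e-05, or adjusted p = 0.517 with an estimated correlation). Myl1 fell by 5.36 ± 0.60, and without normal replicate 1 the median was -0.74. The mean erythrocyte level was 7.55 ± 0.34 (SD, n = 3). Antigen presentation did not pass, with a median of 0.58 and 10 of 12 folds above 0 (adjusted p = 0.287). T and NK cell (-0.08, adjusted p = 0.964), B and plasma cell (-0.10, adjusted p = 0.423), interferon response (-0.05, adjusted p = 0.809), squamous keratinocyte (0.29, adjusted p = 0.809) and immediate early lists (-0.14, adjusted p = 0.809) did not pass either.

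Rb/p53 tumours were compared with p53 tumours to ask what differs between the tumour genotypes. Of the 9 Rb/p53 tumours 7 are labelled as transplants, while the labels do not say whether the p53 tumours were transplanted. Differences between these groups therefore cannot be told from an effect of transplantation. A single gene passed, H2-Ea, which encodes the alpha chain of the class II antigen-presenting molecule H2-E. It was at 6.53 ± 0.19 (SD, n = 9) in Rb/p53 and 8.96 ± 0.84 (SD, n = 3) in p53 tumours, a log2 fold of -2.43 ± 0.25 (limma adjusted p = 0.00820). At an unadjusted p below 0.05 there were 4117 genes, 2117 of them higher. H2-Ea read 8.04, 9.68 and 9.16 on the 3 p53 tumours, at most 6.89 on any Rb/p53 tumour and 7.05 to 8.41 in normal tissue. On the arrays of Rb/p53 tumours it lay at percentile 17.5 to 27.5 of all genes, so it is not shown to be above background there and the size of its fold is not exact. Its call was lost when only MMTV-Cre tumours entered (-2.38, adjusted p = 0.0518), where Nr2f1, a nuclear receptor, passed instead (1.56), and when only the 2 tumours not labelled as transplants did (-2.14, adjusted p = 0.180). Moving p53 replicate 3 to the Rb/p53 tumours gave -2.06 (adjusted p = 0.0520), and leaving out replicate 2 as well, an alternative chosen after the data were seen, gave -1.24 (adjusted p = 0.653). The gene count itself depended on p53 replicates: 1358 genes passed without replicate 3, 2 without replicate 2 (H2-Ea and Gm4876), and without replicate 1 there were 19, among them Alox15, a lipoxygenase, at -3.38. It was 2044 with replicate 3 moved, 12 with replicate 2 left out as well, and 356 with all 17 arrays in the fit.

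E2F targets and DNA replication genes were higher in Rb/p53 tumours by the list test (median log2 fold 0.59, camera adjusted p = 1.35e-09), with 39 of 40 folds above 0. No member passed over all genes and 1 did adjusted over the list alone. The adjusted p was 0.602 with an estimated correlation. The mean level of the list was 10.01 ± 0.18 (SD, n = 9) in Rb/p53 tumours and 9.38 ± 0.94 (SD, n = 3) in p53 tumours, of which replicate 2 read 8.29. Without that replicate the median was 0.08 (adjusted p = 0.208), and without replicate 1 it was 0.90. Mitosis genes had a median of 0.57 (adjusted p = 2.16e-04, or adjusted p = 0.602 with an estimated correlation), with 0 of 27 past the threshold by limma either way. Without p53 replicate 2 the list was called lower (-0.27, adjusted p = 0.00288), and without replicate 1 the median was 0.94. With array weights both calls were lost (0.12, adjusted p = 0.0791, and -0.22, adjusted p = 0.0512). With p53 replicate 2 left out and replicate 3 moved they stood at -0.02 (adjusted p = 0.771) and -0.40 (adjusted p = 8.83e-06). E2f1 (0.32 ± 0.23, adjusted p = 0.405), Ccne1 (0.61 ± 0.26, adjusted p = 0.219), Rbl1 (0.23 ± 0.28, adjusted p = 0.621), Mki67 (0.09 ± 0.24, adjusted p = 0.823) and Cdkn2a (0.61 ± 0.56, adjusted p = 0.501) did not pass.

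Mitochondrial translation genes had a median of 0.22 in the same comparison (adjusted p = 3.24e-05, or adjusted p = 0.602 with an estimated correlation), with 0 of 73 past the threshold over all genes or adjusted over the list alone, and Tufm at 0.33 ± 0.17 (adjusted p = 0.262). This call was lost without p53 replicate 2 (0.04, adjusted p = 0.345), after quantile normalisation again (0.09, adjusted p = 0.0647) and under cyclic loess (0.07, adjusted p = 0.131). Ribosome biogenesis genes (0.18, adjusted p = 0.0245, or adjusted p = 0.708 with an estimated correlation; 0 of 19 either way) were called lower without p53 replicate 2 (-0.19, adjusted p = 0.0364). Their call was lost without Rb/p53 MMTV-Cre replicate 2 or 5 (adjusted p = 0.0687 and 0.0531), and the median rose to 0.36 and 0.43 without p53 replicates 1 and 3. Array weights, the low filter, quantile normalisation again and cyclic loess each ended the ribosome biogenesis call (adjusted p = 0.184 to 0.490), and array weights ended that of mitochondrial translation (0.07, adjusted p = 0.214). Oxidative phosphorylation (0.04, adjusted p = 0.145; 3 higher and 3 lower of 59 adjusted over the list alone), hypoxia and glycolysis (0.12, adjusted p = 0.348) and p53 target genes (0.02, adjusted p = 0.697; 1 higher and 1 lower of 26 adjusted over the list alone) did not pass. Without p53 replicate 1 oxidative phosphorylation (0.08, adjusted p = 0.0178) and hypoxia (0.38, adjusted p = 0.00519) were called higher. With replicate 2 left out and replicate 3 moved hypoxia was called lower (-0.44, adjusted p = 7.42e-04), as was oxidative phosphorylation under cyclic loess (-0.13, adjusted p = 0.0182).

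Cell type lists were also called between the tumour genotypes, again with no member past the threshold over all genes. Each of these calls was lost with an estimated correlation (adjusted p = 0.473 for B and plasma cells and 0.602 for the others). Macrophage markers were lower in Rb/p53 tumours (median -0.75, adjusted p = 3.89e-04; 2 of 17 adjusted over the list alone), as were antigen presentation genes (-0.70, adjusted p = 0.00777; 3 of 12), T and NK cell markers (-0.34, adjusted p = 0.00671; 8 of 16) and B and plasma cell markers (-0.25, adjusted p = 0.00314; 5 of 13). Without p53 replicate 2 these medians were -0.41, -0.38, -0.22 and -0.16. With replicate 3 moved as well, the macrophage median turned to 0.12 (adjusted p = 0.757). That tumour had the highest mean level of all tumours for macrophage markers (12.34) and neutrophil markers (10.55). Endothelial (0.28, adjusted p = 0.00777; 0 of 14) and mesenchymal transition markers (0.42, adjusted p = 0.0139; 4 higher and 1 lower of 22) were higher. They stood at -0.04 (adjusted p = 0.592) and 0.17 (adjusted p = 0.208) without p53 replicate 2, at 0.55 and 0.72 without replicate 1, and at 0.52 and 0.64 without replicate 3. The endothelial median was -0.11 (adjusted p = 0.757) with replicate 2 left out and replicate 3 moved. Luminal markers (0.36, adjusted p = 0.0113; 1 of 27) lost their call without p53 replicate 1 (0.12, adjusted p = 0.0916) or Rb/p53 MMTV-Cre replicate 3 (0.24, adjusted p = 0.0511). Milk protein genes (0.98, adjusted p = 0.0105; 0 of 11) lost theirs without p53 replicate 1 (0.80, adjusted p = 0.103) or MMTV-Cre replicate 2 (0.80, adjusted p = 0.0581). Interferon response genes were higher (0.60, adjusted p = 0.00347; 0 of 16), a call lost without p53 replicate 3 (0.30, adjusted p = 0.166). Squamous keratinocyte markers (-0.19, adjusted p = 0.0457; 0 of 18) were called no longer without p53 replicate 2 (0.02) or MMTV-Cre replicate 2, 4, 5 or 7 (adjusted p = 0.0510, 0.0580, 0.0531 and 0.0625). Basal, fibroblast, adipocyte, neutrophil, muscle and immediate early lists did not pass (adjusted p = 0.642, 0.555, 0.642, 0.348, 0.934 and 0.0521). The immediate early list passed without Rb/p53 MMTV-Cre replicate 1, 3 or 5, Ad-Cre replicate 1 or p53 replicate 2. Array weights ended the calls on macrophage (-0.15, adjusted p = 0.0719), antigen presentation (-0.24, adjusted p = 0.0719), endothelial, mesenchymal and squamous lists. The low filter ended those on endothelial, luminal, mesenchymal, milk protein and squamous lists, and cyclic loess those on endothelial, mesenchymal, squamous and B and plasma cell lists. Quantile normalisation again ended the squamous and B and plasma cell calls. Moving p53 replicate 3 ended the calls on macrophage (-0.72, adjusted p = 0.0699), antigen presentation, B and plasma cell and interferon lists. With only the tumours not labelled as transplants the mesenchymal, interferon, squamous and B and plasma cell calls were lost and adipocyte markers were called higher (0.43, adjusted p = 0.0133).

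Lineage genes fixed in advance did not pass between the genotypes: Krt8 (0.18 ± 0.62), Krt18 (0.80 ± 0.69), Krt5 (-0.85 ± 0.45), Krt14 (0.06 ± 0.54), Trp63 (0.35 ± 0.17), Esr1 (-0.31 ± 0.19), Vim (0.07 ± 0.09), Cdh1 (-0.08 ± 0.53) and Epcam (1.64 ± 0.97) had adjusted p-values of 0.244 to 0.957. Vim was near the top of the range in every tumour, at 14.02 ± 0.07 (SD, n = 9) and 13.96 ± 0.16 (SD, n = 3).

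Met, Yap1, Birc2 and Birc3 and their chromosomal neighbours were fixed in advance as candidates for high values in single tumours. Met encodes the hepatocyte growth factor receptor, Yap1 a transcriptional coactivator of the Hippo pathway, and Birc2 and Birc3 inhibitors of apoptosis. None passed between Rb/p53 and p53 tumours (adjusted p = 0.804, 0.300, 0.584 and 0.942) or against normal tissue (adjusted p = 0.137, 0.259, 0.437 and 0.228 for Rb/p53 tumours and 0.422, 0.688, 0.996 and 0.407 for p53 tumours). High values sat in single tumours. Yap1 read 13.51, 13.46 and 12.15 in MMTV-Cre Rb/p53 replicates 1 and 7 and Ad-Cre replicate 1, and at most 10.75 on any other array. Birc2 read 12.47, 12.43 and 10.51 in those tumours and at most 9.30 elsewhere. Of Yap1, Birc2, Birc3, Tmem123, Dcun1d5 and Dync2h1, 6, 6 and 5 were more than 1 log2 unit above the median of the other tumours there. Met read 13.36 in MMTV-Cre Rb/p53 replicate 2, 13.60 in Ad-Cre replicate 2, and 13.39 and 13.26 in p53 replicates 1 and 3, against 6.82 in p53 replicate 2 and 9.73 to 10.10 in normal tissue. Its neighbours Capza2, Cav1, Cav2, Tes and St7 were high together with it in p53 replicates 1 and 3 (6 of 6 genes) and MMTV-Cre replicate 2 (5 of 6), but in Ad-Cre replicate 2 only Met and Capza2 were.

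**Figure D3:**
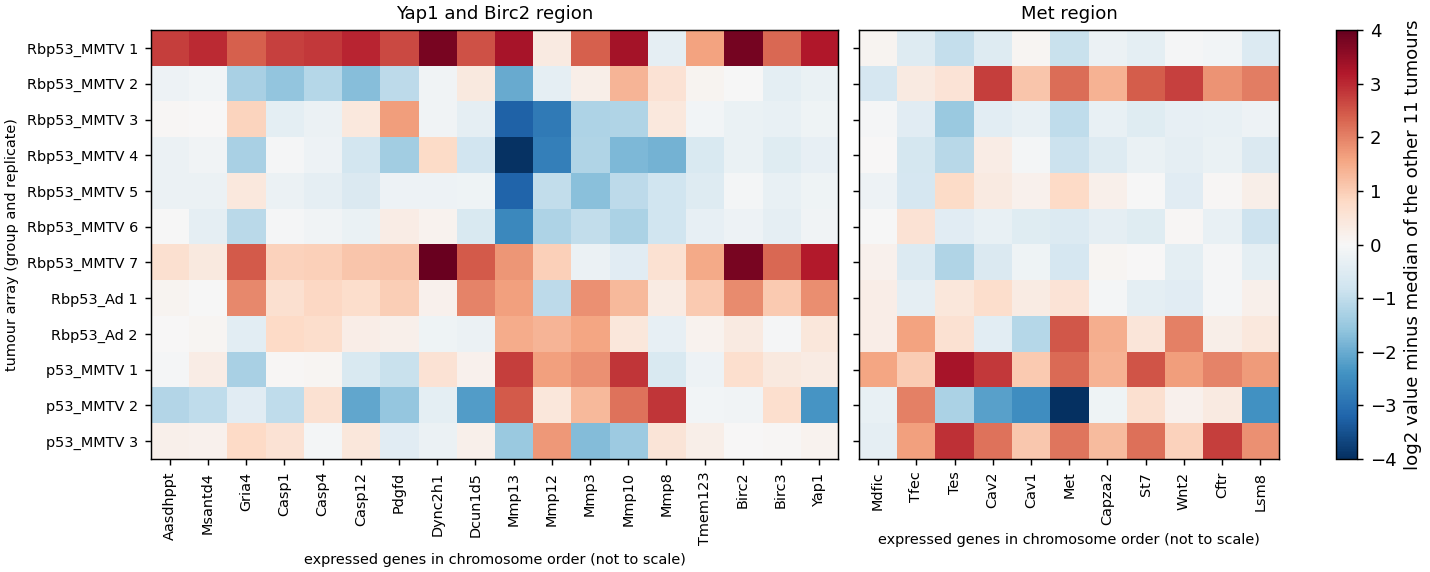
Log2 value of each expressed gene minus the median of the other 11 tumours (colour) in the Yap1 and Birc2 region and in the Met region, for the 12 tumours (vertical axis, group and replicate). Genes are in chromosome order on the horizontal axis and not to scale. Runs of high neighbours appear in MMTV-Cre Rb/p53 replicates 1 and 7 and Ad-Cre replicate 1 on the left, and in MMTV-Cre Rb/p53 replicate 2 and p53 replicates 1 and 3 on the right.

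Within Rb/p53 tumours, 2 Ad-Cre tumours were set against 7 MMTV-Cre tumours to see whether the delivery of Cre mattered. Both Ad-Cre tumours are labelled as transplants, against 5 of the 7 MMTV-Cre tumours. No fit was limited to transplants, so an effect of delivery was not separated from one of transplantation or parity. Pcdh7, a protocadherin that mediates cell adhesion, was the 1 gene past the threshold by limma (log2 fold 2.06 ± 0.19, adjusted p = 0.00335), at 9.37 ± 0.29 (SD, n = 2) and 7.31 ± 0.23 (SD, n = 7); normal tissue read 9.11 to 9.36. At an unadjusted p below 0.05 there were 412 genes, and Rb1 did not pass (0.08 ± 0.25). The count was 30 without Ad-Cre replicate 1 and 8 without Ad-Cre replicate 2. Lists called higher in Ad-Cre tumours were neutrophil markers (median 0.87, adjusted p = 0.00128), p53 targets (0.16, adjusted p = 0.00507), oxidative phosphorylation (0.08, adjusted p = 0.00173), mitochondrial translation (0.07, adjusted p = 0.0271), endothelial markers (0.15, adjusted p = 0.0391) and antigen presentation (0.33, adjusted p = 0.0469). Skeletal muscle was lower (-0.21, adjusted p = 3.78e-04). No member of them passed over all genes or adjusted over the list alone, and with an estimated correlation none was called (adjusted p = 0.275 to 0.860). Without Ad-Cre replicate 2 neutrophil markers (0.29, adjusted p = 0.287), p53 targets (0.11, adjusted p = 0.481), oxidative phosphorylation (0.09, adjusted p = 0.204), mitochondrial translation (0.01, adjusted p = 0.696), antigen presentation (0.05, adjusted p = 0.696) and muscle (-0.17, adjusted p = 0.0539) lost their calls. Without Ad-Cre replicate 1 the medians of neutrophil markers, antigen presentation and mitochondrial translation were 1.52, 0.80 and 0.15, and endothelial markers lost their call (adjusted p = 0.331). Further lists were called with 1 Ad-Cre tumour left out. Without replicate 2 these were luminal (-0.30, adjusted p = 0.0263), macrophage (-0.32, adjusted p = 0.0496), basal (-0.24, adjusted p = 0.0105), interferon (-0.51, adjusted p = 8.20e-04) and immediate early lists (-0.39, adjusted p = 2.38e-04), all lower. Without replicate 1 luminal (0.28, adjusted p = 0.0227), interferon (0.41, adjusted p = 0.0138), milk protein (1.92, adjusted p = 0.00371), fibroblast (0.24, adjusted p = 0.0243) and T and NK cell lists (0.04, adjusted p = 0.0207) were called higher and hypoxia lower (-0.33, adjusted p = 0.0126). Single MMTV-Cre replicates mattered for endothelial markers (2, 3, 4 or 7; highest adjusted p = 0.133, and median 0.23 without 6), antigen presentation (2, 4 or 6, and p53 replicates 2 or 3; highest adjusted p = 0.138) and mitochondrial translation (4 or 6; highest adjusted p = 0.133). Under cyclic loess only the neutrophil and muscle calls remained, and the low filter, quantile normalisation again and array weights each ended the antigen presentation and endothelial calls. The mitochondrial translation call was lost with the low filter (adjusted p = 0.116) and after quantile normalisation again (0.03, adjusted p = 0.254). That on antigen presentation was also lost with p53 replicate 3 moved (0.20, adjusted p = 0.143) and with only the 9 Rb/p53 arrays in the fit (adjusted p = 0.0752).

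Transplanted MMTV-Cre Rb/p53 tumours (n = 5) were compared with the nulliparous and the parous tumour (n = 2). Wap, whey acidic protein, fell from 12.16 ± 0.90 (SD, n = 2) to 7.56 ± 0.14 (SD, n = 5), a log2 fold of -4.60 ± 0.31 (limma adjusted p = 0.00651), and Glycam1, a mucin of milk, fell by 5.26 ± 0.30. The imprinted gene Sgce rose by 2.74 ± 0.16, from 8.60 ± 0.02 (SD, n = 2) to 11.34 ± 0.23 (SD, n = 5). The other 2 of 5 genes past the threshold were immunoglobulin kappa segments (-1.81 and -2.15). The call on the segment at -1.81 was lost without MMTV-Cre replicate 2, and that on the segment at -2.15 without replicate 3 or 7. At an unadjusted p below 0.05 there were 1579 genes. When the spread was taken from all 12 tumours the call on Sgce was lost (adjusted p = 0.826). The gene count was 158 without MMTV-Cre replicate 1 and 10 without replicate 2.

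Of 11 milk protein genes 2 fell and none rose in the transplants (6 fell adjusted over the list alone; median -1.65, camera adjusted p = 8.03e-13, or adjusted p = 0.407 with an estimated correlation). Ribosome biogenesis (-0.26, adjusted p = 1.04e-04), mitochondrial translation (-0.09, adjusted p = 9.93e-04), adipocyte (-0.36, adjusted p = 9.93e-04), luminal (-0.38, adjusted p = 0.00615), basal (-0.24, adjusted p = 0.0232), neutrophil (-0.49, adjusted p = 0.0206), B and plasma cell (-0.03, adjusted p = 0.0206; 3 lower adjusted over the list alone) and T and NK cell lists (-0.08, adjusted p = 0.0328; 2 lower adjusted over the list alone) were called lower. With an estimated correlation none was called (adjusted p = 0.407 to 0.892). The B and plasma cell call was carried by a few members, as its mean fold of -0.36 lay far from the median. The T and NK list had a mean fold of 0.02, opposite in sign to its median and test. Without MMTV-Cre replicate 2 luminal (-0.08, adjusted p = 0.790), adipocyte (-0.18, adjusted p = 0.313) and neutrophil (-0.24, adjusted p = 0.543) calls were lost and the ribosome biogenesis median was -0.16. Without replicate 1 basal (-0.003, adjusted p = 0.314), mitochondrial translation (-0.02, adjusted p = 0.164) and T and NK calls (0.04, adjusted p = 0.219) were lost. Hypoxia was called lower without replicate 1 (-0.27, adjusted p = 4.15e-04) and higher without replicate 2 (0.44, adjusted p = 1.33e-08), and fibroblast markers were called higher (0.71, adjusted p = 0.0225) and lower (-0.57, adjusted p = 7.05e-04) in these settings. Calls were further lost without replicate 4 for luminal and basal, 5 for basal and T and NK, 6 for T and NK, and 7 for luminal lists (highest adjusted p = 0.156). The low filter ended the B and plasma cell (0.01, adjusted p = 0.410), T and NK and neutrophil calls, and ranks ended the B and plasma cell call (adjusted p = 0.261) and that of T and NK cells (adjusted p = 0.210).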

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

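Among the tests in this part, those of other splits and of matched random lists were fixed before their results were seen; those of leaving out p53 replicate 2, of loss of Rb, of the chromosomal neighbours and of H2-Ea were chosen only after the result was seen. The rule that sought a single array far from the rest of its group is expected to pick about 1 in 20 groups by chance. It was applied to 135 genes and lists in each of 2 groups and picked 7 in MMTV-Cre Rb/p53 tumours and 5 in normal tissue.

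In MMTV-Cre Rb/p53 tumours, Cdkn2a was at 8.30 on replicate 4, and the nearest other tumour was at 10.03. Cxcr2 was at 6.45 on the same array, the nearest being 8.27. Krt18 was at 12.32 on replicate 2, with the nearest tumour at 10.96. Elf5 (9.53, nearest 7.70) and Ces1d (10.55, nearest 6.75) were also highest on replicate 2, the parous tumour. Slc2a1 was lowest on replicate 1 at 11.79, the nearest being 12.47. The mean of the squamous keratinocyte list was 7.42 on replicate 3, with the nearest at 7.03.

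In normal tissue, Wap was at 12.12 on replicate 4, and the nearest other sample was at 8.94. Tnc was highest on the same array at 8.85, the nearest being 8.22. Oxtr was at 8.80 on replicate 5 (nearest 10.02) and Junb at 7.95 on it (nearest 8.52). Mrps6 was lowest on replicate 2 at 11.29, with the nearest at 11.69.

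H2-Ea differed between tumour genotypes by -2.43 log2 units, as the only gene past the threshold there. In Rb/p53 tumours it lay at percentile 17.5 to 27.5 of the genes on each array, so it is not shown to be above background and the size of the difference is not exact. Fewer cells that express class II genes could lower it. Of the 7 Rb/p53 tumours labelled as transplants, 6 had a class II mean (H2-Aa, H2-Ab1, H2-Eb1 and Cd74) at least that of the lowest p53 tumour. In these 6 the class II mean was thus not below all p53 tumours. H2-Ea lay below every p53 tumour in all 6, but this held for every Rb/p53 tumour and was known beforehand. The count therefore cannot decide on this cause in transplants. The 2 tumours not so labelled had class II means of 9.95 and 10.27 against 10.50 in the lowest p53 tumour. Thus 0 of them could be tested, and fewer class II cells stay open there too. A first test of the same cause, an exact permutation of H2-Ea minus the class II mean over 220 splits (-1.96, p = 0.0864), did not reach its bound; the count replaced it after the values had been seen. An inherited class II haplotype without H2-Ea expression could also act, since the strain background is mixed. H2-Eb1 minus H2-Aa, compared after the values were seen, was -1.10 to 0.07 in Rb/p53 transplants. It was -2.35 and -2.58 in MMTV-Cre replicates 1 and 2 and -3.67 to -3.05 in p53 tumours. For H2-Ea the highest Rb/p53 tumour read 6.89 and the lowest p53 tumour 8.04. With the states divided by genotype a haplotype cannot be told from an effect of genotype, nor from transplantation in the 7 Rb/p53 transplants. That division rests on the place of p53 replicate 3 (9.16), whose title names the Rb/p53 model: if the title is right, an Rb/p53 tumour was in the high state and the states were not divided by genotype.

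The E2F, mitosis and mitochondrial translation lists were called higher in Rb/p53 than in p53 tumours, each with an adjusted p of 0.602 with an estimated correlation, and 1 p53 array may carry this. Without p53 replicate 2 the medians were 0.0785 (adjusted p = 0.208), -0.27 (adjusted p = 0.00288) and 0.0358 (adjusted p = 0.345), so none was called higher any longer. The narrower range of values on that array could produce such a shift: the mitochondrial list lay at percentile 4.28 of matched random lists, inside their central range, but the E2F and mitosis lists lay at percentile 0 and 0, with medians of -1.63 and -2.02 relative to the other tumours, which argues against the range as their whole cause. Loss of Rb, which frees E2F factors, could raise E2F targets in every Rb/p53 tumour; against the remaining p53 tumours the list's adjusted p was 0.896 with an estimated correlation, which cannot tell.

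Neighbouring genes were high together in single tumours around Yap1 and Birc2 and around Met. In the highest window of 10 neighbours, 10, 6 and 8 genes were high in the Yap1 region on MMTV-Cre Rb/p53 replicates 1 and 7 and Ad-Cre replicate 1, and 8, 10 and 9 in the Met region on MMTV-Cre Rb/p53 replicate 2 and p53 replicates 1 and 3. The windows are not the same genes: that of MMTV-Cre replicate 1 ran from Aasdhppt to Mmp13, beside Yap1, and those of the other Yap1 arrays from Dcun1d5 to Yap1. Brightness of the whole array could raise many genes, but shuffled gene orders, which keep each array's values, gave at most 6 (median highest count 4). The lowest count was 8 for Met, above every shuffled order, and 6 for Yap1, where MMTV-Cre replicate 7 only equalled the shuffled orders. The arrays entered only with at least 5 of the 6 locus genes high. A Met count as low as the shuffled median could therefore not occur. The counts at Met and Yap1 thus cannot decide on brightness. Array medians on MMTV-Cre Rb/p53 replicates 1 and 7 and Ad-Cre replicate 1 were 7.75, 7.74 and 7.74, within the tumours' 7.74 to 7.83. Normalisation between arrays makes such medians alike, so they do not test brightness. The 6 genes fixed around Yap1 lay a median of 2.88, 2.81 and 1.45 above the other tumours there. The arrays were chosen by these same genes, so these values cannot decide on brightness either. Gain of a chromosome region might also act, but the arrays counted were chosen because at least 5 of the 6 locus genes were high on them. Arrays that would fail could not enter, so their lowest counts (8 for Met and 6 for Yap1) cannot decide on a gain. Ad-Cre replicate 2, with Met at 13.60, was left out, with 2 of 6 Met region genes high and at most 4 in a window. Runs beyond those of shuffled orders also held gene families elsewhere, so they are not specific to a gain, and DNA was not analysed here.

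Other splits of the same arrays ask whether chance can be excluded. The real split is among those counted. Between tumour genotypes 22 of 100 splits called at least as many genes as the real split (1; highest other 12) and 6 of 100 as many lists (14; highest other 16), so chance was not excluded for either. For Rb/p53 tumours against normal tissue the count was 1 of 100 for genes (5503, highest other 997). That is the lowest share these splits allow, so chance is unlikely. For lists it was 2 of 100 (17, highest other 18). That share is below 0.05, but another split called more lists, so chance is unlikely rather than excluded there. For p53 tumours against normal tissue the count was 1 of 56 for genes (4073, highest other 315), again the lowest share possible, so chance is unlikely. For lists it was 9 of 56 (12, highest other 15), where chance was not excluded.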

How the results depend on the processing

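No paired analysis was possible because the labels carry no shared replicate numbers that tie a tumour to a normal sample. The number of arrays limits precision. Named genes were counted as unchanged where they kept their side of the threshold and, if called, their direction. For Rb/p53 tumours against normal tissue this held in 2228 of the gene and setting combinations (60 weaker, 7 stronger). It held in 1506 for p53 tumours (71 weaker, 9 stronger). No gene called in either setting reversed, and changes of sign in genes not called were not counted. Unless stated, the cause of a change was not tested.

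Between tumour genotypes 1 gene and 14 lists were called. The gene count was 3 with array weights, 2 with the low filter, 2 after quantile normalisation again, 2 under cyclic loess and 5 over all probe sets. It was 356 with all 17 arrays in the fit, 0 with only tumours not labelled as transplants, 2044 with p53 replicate 3 moved, and 12 with p53 replicate 2 left out as well. Leaving out 1 array gave 1 to 1358 genes, the latter without p53 replicate 3. Lists called numbered 5 with array weights, 8 with the low filter, 9 under cyclic loess, 0 with an estimated correlation and 6 with p53 replicate 2 left out and replicate 3 moved. Rb1 stayed at -0.86 but passed with all 17 arrays (adjusted p = 0.0390), and ranged from -1.10 to -0.56 over arrays left out.

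Directions turned in the same comparison. The mitosis median was -0.22 with array weights, -0.40 in the added alternative (p53 replicate 2 left out and replicate 3 moved, chosen after the data were seen), and -0.27 to 0.94 over arrays left out. Ribosome biogenesis was -0.15 with array weights, -0.17 in the added alternative and -0.19 to 0.43 over arrays left out. Oxidative phosphorylation was -0.13 under cyclic loess. In the added alternative hypoxia was called lower at -0.44, macrophage markers 0.12 and endothelial markers -0.11, the last -0.043 to 0.55 over arrays left out. The lowest of each of these ranges came without p53 replicate 2, and array weights give the least weight to arrays that stand apart.

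For Rb/p53 tumours against normal tissue 1630 genes passed with a fold of at least 1 as well, and 2 lists (adipocyte and basal) with an estimated correlation. Leaving out 1 array gave 4407 to 6725 genes and 15 to 18 lists. For p53 tumours 1617 genes passed with a fold of at least 1, and 2 lists, the same, with an estimated correlation. Leaving out 1 array gave 3226 to 5355 genes and 10 to 13 lists. Rb1 stayed at -0.81 with only the 8 arrays compared in the fit (adjusted p = 0.0598), was -0.75 with p53 replicate 3 moved (adjusted p = 0.0556), and ranged from -1.11 to -0.58 over arrays left out. Mitochondrial translation ranged from -0.27 to 0.013.

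For Ad-Cre against MMTV-Cre tumours the gene count was 4 under cyclic loess, 2 over all probe sets and 1 to 30 over arrays left out. Lists numbered 4 with the low filter, 2 under cyclic loess, 0 with an estimated correlation and 6 to 12 over arrays left out. Over those arrays mitochondrial translation ranged from 0.0088 to 0.15, luminal markers from -0.30 to 0.28, macrophage markers from -0.32 to 0.32, interferon response from -0.51 to 0.41 and antigen presentation from 0.049 to 0.80. Both ends were calls for luminal and interferon lists, and for macrophage markers the lower end was, each without 1 of the Ad-Cre tumours. With 1 Ad-Cre tumour left it is taken to vary like the other groups. For transplanted against other tumours 16 probe sets passed over all probe sets, 0 lists passed with an estimated correlation, and leaving out 1 array gave 4 to 158 genes, hypoxia medians of -0.27 to 0.44 and fibroblast medians of -0.57 to 0.71, where both ends of each were calls, without MMTV-Cre replicate 1 or 2.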

Other observations

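All observations in this part were chosen only after the result was seen. Sgce lies beside Peg10, another imprinted gene that is expressed from the paternal copy. Among MMTV-Cre Rb/p53 tumours Peg10 was at 6.97 and 7.32 in replicates 1 and 2 and between 9.90 and 10.99 in the transplants, and it passed the threshold with the low filter (3.33, adjusted p = 0.0360). Sgce read 9.75, 8.11 and 10.94 on p53 replicates 1 to 3, 11.76 and 10.34 in the Ad-Cre tumours and 11.23 to 11.65 in normal tissue.

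Brinp3, among the largest rises of Rb/p53 tumours against normal tissue, also passed between tumour genotypes with array weights (1.83), the low filter (2.19), quantile normalisation again (2.04) and cyclic loess and without p53 replicate 1 (2.37), with adjusted p-values of 0.0240 to 0.0435.

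On p53 replicate 2, against random lists of the same mean level, macrophage, neutrophil and antigen presentation lists lay at percentile 100, T and NK cell markers at 99.2 and oxidative phosphorylation at 97.47. Endothelial markers lay at 0.12, mesenchymal transition markers at 0.82, milk protein genes at 0.92 and ribosome biogenesis at 1.83.

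H2-Eb1 minus H2-Aa was -1.10 to 0.07 in the Rb/p53 transplants, -2.35 and -2.58 in MMTV-Cre replicates 1 and 2, -3.67 to -3.05 in p53 tumours and -3.59 to -3.20 in normal tissue.

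Runs of neighbouring high genes beyond those of shuffled orders also occurred outside the Yap1 and Met regions. They held caseins in MMTV-Cre replicate 2, Cxcl chemokines and granzymes in Ad-Cre replicate 2, and the Slamf and Clec4 families in p53 replicate 2.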
